A study of Mus musculus with 11 samples.

How the data were processed

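RNA was measured by sequencing in 11 mouse libraries of the C57BL/6J strain. Per the labels' protocols, leukemic cells (B-ALL) came from lymph nodes of Ebf1+/- Pax5+/- mice that had developed B cell acute lymphoblastic leukemia, and each of 3 mice, numbered 686, 713 and 760, gave 2 libraries. Per the labels' protocols, the dHet proB cells carried Ebf1+/- Pax5+/- Rag2-/-, were taken as c-Kit+ cells from fetal liver and were kept for a short time on OP9 stromal feeder cells with IL-7, Flt3 ligand and SCF. They gave 3 libraries. The sample taken as library 3 is titled replicate 3, while its source name says replicate 2, as does that of library 2. The wt proB cells were, per the labels, sorted from bone marrow of mice with intact Ebf1, Pax5 and Rag2 as the FrBC fraction, and gave 2 libraries. Genotype at Rag2, tissue, culture and leukemia therefore change together between the groups, and none of them could enter the model as a term of its own. The markers of the sort gates are not given in the sources used here.

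Per the submitters' processing notes, reads were handled with bcl2fastq (versions 2.20.0.422 and 0.3.1 are both named), STAR 2.5.3a, Cufflinks 2.2.1, Cuffdiff and Cuffnorm 2.2.1 on the mouse genome build mm9. The authors deposited, for each library, a table of FPKM (fragments scaled by transcript length and by the number of mapped fragments) for the same 24319 gene symbols. Which scaling Cuffnorm applied and which gene annotation was used are not given in the sources used here. The FPKM sums ranged from 505261 to 638953 per library, so the values were not scaled to a common sum. The depth of each library is unknown, since the tables hold no counts, and no counting error is given for any value. The tables hold no mitochondrial genes and no immunoglobulin or T cell receptor segments. No genome coordinates are printed, because the reference tables at hand belong to another build than mm9; the RefSeq gene table of assembly GRCm38.p6 was used only for which genes neighbour each other, and GENCODE M21 transcripts were used only for shared sequence words.

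FPKM values were transformed to log2(FPKM + 1). This pseudocount of 1 shrinks fold changes of genes with low FPKM. The libraries of each B-ALL mouse were averaged on the log2 scale, so the mouse was the replicate, and 8 units entered the fit: 3 B-ALL mice, 3 dHet proB libraries and 2 wt proB libraries. Genes with FPKM of 1 or more in at least 2 units were tested, which left 11110. limma 3.58.1 (R 4.3.3, statmod 1.5.0) was fitted to all 3 groups with a shared spread and a mean-variance trend, two-sided, and p-values were adjusted by Benjamini and Hochberg at a threshold of 0.05 in each comparison. The 3 mice were compared by the limma F test on all 11 libraries in 5 groups, with 11293 genes tested; that test measures the mice against the spread between libraries, not between animals. The labels do not say whether the dHet proB or the wt proB libraries came from separate animals or cultures, so p-values there measure the spread between these libraries, which may be technical. With 3 mice against 2 or 3 libraries, no rank or permutation test of a single gene could reach 0.05, and the adjusted p-values rest on the spread that limma shares between genes and groups.

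The 23 gene lists, with 438 genes of which 436 were in the tables, and the rule for naming genes were fixed before the data were examined. They cover IL-7 signalling, STAT5 targets, the MYC network, MYC targets, folate metabolism, serine and nucleotide synthesis, cell cycle, glycolysis, genes activated by PAX5, genes repressed by PAX5, genes activated by EBF1, progenitor genes, V(D)J recombination, mature B cells, genes often mutated in B-ALL, interferon-stimulated genes, stress genes, and markers of T cells, NK cells, myeloid cells, red cells and megakaryocytes, plasma cells and stroma. Each list was tested with limma camera at its preset correlation of 0.01, adjusted over 69 tests, and again with an estimated correlation and with fry. The test of fry asks whether a list's genes move, on balance, one way, and does not compare the list with other genes. Genes named in every comparison were Ebf1, Pax5, Rag1, Rag2, Myc, Il7r, Mthfd2 and Shmt2. Besides these, each comparison names the 6 largest rises and the 6 largest falls among genes that passed the test, had a mean FPKM of 10 or more in the higher group and had every library of the higher group above every library of the lower; predicted gene models were left out. Each list contributes up to 2 members per direction with the largest change among those that passed. For the mice, the 3 genes per mouse with the largest excess over the other mice are named. A few genes that these rules name are not reported here. Genes and marker lists chosen later are said to be so where they appear.

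Each step was tested on simulated data with 66 or 67 changed genes per fold. For B-ALL against wt proB (10707 genes tested), 86.4% of genes changed by 4-fold, 28.4% of those changed by 2-fold and 1.49% of those changed by 1.5-fold were called. For B-ALL against dHet proB (10714 genes) the shares were 87.9%, 31.3% and 4.48%, and for dHet proB against wt proB (10716 genes) 86.4%, 31.3% and 0%. For the mice (10655 genes) they were 84.8%, 46.3% and 0%. Unchanged genes called numbered 9, 7, 2 and 7 in that order. The list test was run with the MYC targets raised by 1.5-fold in B-ALL and with genes simulated as independent. It called 2 of 2 raised list tests and 0 of 67 others. The marker, neighbour and split tests described below were not simulated in this way. In these simulations most changes of 4-fold were detected and most of 2-fold or less were missed. Far more genes were called in the data, among 11110 tested. They numbered 2017 in B-ALL against wt proB, 2832 in B-ALL against dHet proB and 964 in dHet proB against wt proB. The adjusted threshold is then less strict, so the simulated shares do not carry over to the data.

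Alternatives tried were pseudocounts of 0.1 and 0.5, no filter, a filter of FPKM 5, rescaling to TPM, median-centred values, quantile normalization, all 11 libraries as independent samples, the mouse as a random effect, the replicate number as a block, only the 2 compared groups in the fit, eBayes without trend or with a robust prior, and leaving out each library and each mouse. For the mice, a fit of only the 6 B-ALL libraries was added to these. After the values were seen, 2 more were added: leaving out mouse 713 together with dHet proB library 3, and using only library 2 of each B-ALL mouse. Where a group was left with a single library, that library is assumed to vary like the other groups. Leaving out a library of a group that is not compared does not move a gene's log2 fold change. It changes the spread and which genes pass the filter, so a list's median can still move. A gene that did not pass the test and changed sign under an alternative was counted as reversed, whereas a list was counted as reversed only if it passed in either setting.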

Results

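Gene expression was measured in leukemic cells of 3 Ebf1+/- Pax5+/- mice with B cell acute lymphoblastic leukemia (B-ALL, 2 libraries per mouse). It was also measured in 3 libraries of cultured Ebf1+/- Pax5+/- Rag2-/- fetal liver proB cells (dHet proB) and in 2 libraries of sorted wild-type bone marrow proB cells (wt proB). EBF1 and PAX5 are transcription factors that B cells need to take up and keep their identity. The series asks how gene expression differs between leukemic, pre-leukemic and normal proB cells. Levels are given as mean FPKM ± SD over n = 3 B-ALL mice, n = 3 dHet proB libraries and n = 2 wt proB libraries. Changes are given as log2 fold changes of FPKM + 1 with the limma adjusted p. The depth of the libraries is unknown. Each library had a value above 0 for 13251 to 14947 of the 24319 genes, and between 9850 and 10595 genes reached FPKM 1.

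The genes targeted in these mice were read first in every library. Ebf1 had FPKM of 170 and 151 in the libraries of mouse 686, 212 and 185 in mouse 713, and 189 and 155 in mouse 760. In dHet proB it had 295, 369 and 283, and in wt proB 297 and 542. Pax5 had 52.8 and 46.2, 38.1 and 40.7, and 35.3 and 51.7 in the same mice. Its values were 99.0, 88.7 and 70.9 in dHet proB and 101 and 57.2 in wt proB. Rag2, a subunit of the V(D)J recombinase, had 12.7 and 11.1, 16.6 and 15.4, and 13.5 and 14.0 in the mice. It had 12.6, 10.2 and 8.57 in dHet proB and 37.8 and 31.1 in wt proB. Rag2 transcript was thus listed in every library labelled Rag2-/-. A value for the whole gene does not show which part of the transcript remains. Neither Ebf1 nor Pax5 passed the test between dHet proB and wt proB, at adjusted p = 0.495 and 0.769.

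Libraries of the same mouse were alike (Pearson r across genes 0.981 to 0.993), and libraries of different leukemic mice less so (0.930 to 0.969). B-ALL and dHet proB libraries had r of 0.878 to 0.911. No libraries held identical values. The first principal component, with 41.5% of the variance, separated the 6 B-ALL libraries from all proB libraries. The second, with 22.2%, set the wt proB libraries apart, and the third, with 15.7%, set mouse 713 apart from the other libraries. The libraries of a mouse also differed for a subset of genes. Of the tested genes, 415 were lower by 2-fold or more in library 1 than in library 2 of mouse 686, 180 in mouse 713 and 30 in mouse 760. In the opposite direction there were 21, 18 and 10. The difference between the libraries had an r across genes of 0.64 between mice 686 and 713, and 156 genes were lower in library 1 of both.

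**Figure D1:**
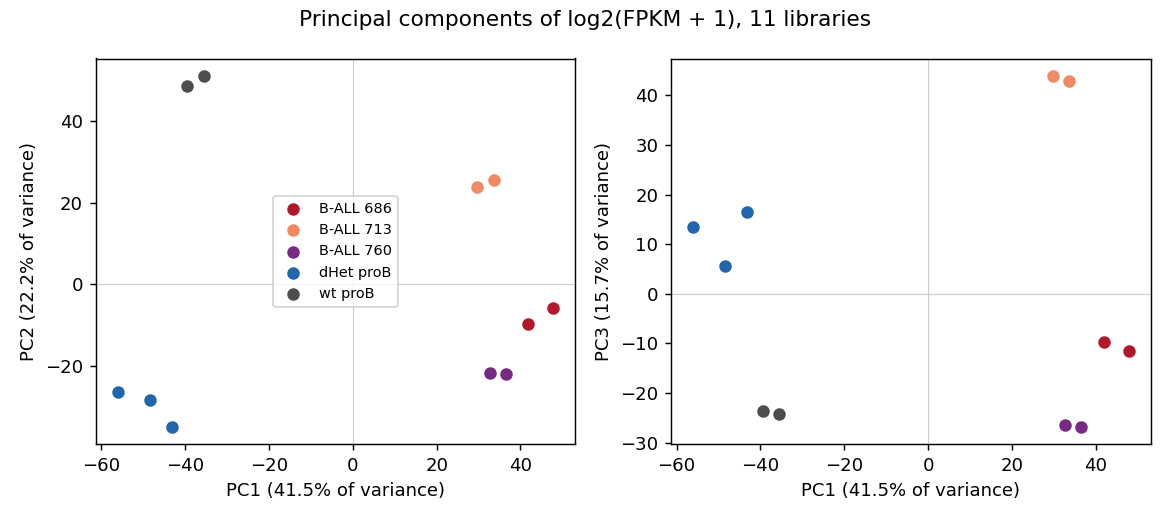
Principal components 1 and 2 (left) and 1 and 3 (right) of log2(FPKM + 1), in units of the component scores, with 1 point per library and the group shown by colour. On component 1 the B-ALL libraries lie between 29.7 and 47.9 and the proB libraries between -56.1 and -35.5. The wt proB libraries lie at 51.0 and 48.5 on component 2, and the libraries of mouse 713 at 42.9 and 43.9 on component 3.

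Leukemic cells were first compared with wt proB cells. The largest rises were in Rnase12, a member of the ribonuclease A family, at 1278 ± 237 FPKM in B-ALL against 11.3 ± 1.18 in wt proB (log2 6.69, adjusted p = 0.000857). The cadherin gene Cdh17 rose to 144 ± 141 from 0.381 ± 0.280 (6.14, adjusted p = 0.00256) and Pnp2, a purine nucleoside phosphorylase, to 210 ± 96.7 from 3.46 ± 0.763 (5.46, adjusted p = 0.00251). Crisp1 rose by 5.35 (adjusted p = 0.000221), the myosin light chain Myl10 by 5.30 (1230 ± 579 against 28.3 ± 3.64) and the interferon-induced membrane protein Ifitm1 by 5.26 (417 ± 550 against 4.43 ± 1.96). The largest falls were in Siglech, a receptor of plasmacytoid dendritic cells, from 105 ± 38.8 to 0.693 ± 0.827 (-6.03, adjusted p = 0.000128). Fcrla fell from 249 ± 64.1 to 10.4 ± 16.8 (-5.80) and the neutrophil granule gene Ngp from 179 ± 49.0 to 6.00 ± 9.78 (-5.78). Fos, part of the AP-1 transcription factor, fell from 70.5 ± 27.4 to 0.261 ± 0.0915 (-5.77, adjusted p = 8.93e-05). The T and NK cell surface gene Cd7 fell from 140 ± 70.7 to 1.60 ± 0.294 (-5.68) and Cox6a2 from 140 ± 40.7 to 3.0 ± 1.68 (-5.20). In dHet proB, Siglech, Fcrla, Ngp, Fos, Cd7 and Cox6a2 had a mean of 0, 27.7, 0.702, 1.40, 0 and 8.88 FPKM. The wt proB libraries held transcripts of other cell types, described below, and their part in these falls was not tested. In total 905 genes were higher and 1112 lower in B-ALL among 11110 tested, of which 514 and 798 changed by 2-fold or more.

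Of the genes named in every comparison, Shmt2, the mitochondrial serine hydroxymethyltransferase, was higher in B-ALL than in wt proB at 226 ± 44.8 against 66.1 ± 5.50 FPKM (log2 1.74, adjusted p = 0.0119). Ebf1 (-1.19, adjusted p = 0.0203) and Rag2 (-1.26, adjusted p = 0.00678) were lower. Myc had 342 ± 119 against 75.5 ± 10.0 FPKM and did not pass (2.10, adjusted p = 0.229), although it passed in 4 of 29 other settings, at adjusted p = 0.0489 without dHet proB library 3. Pax5 (-0.78, adjusted p = 0.0679) and Rag1 (-1.09, adjusted p = 0.0536) did not pass either. Rag1 passed in 11 of 29 other settings (adjusted p = 0.00604 without dHet proB library 2) and Pax5 in 4 (adjusted p = 0.0244 after rescaling to TPM). Neither did Il7r (0.35) or the folate enzyme Mthfd2 (0.07). The value for Mthfd2 changed sign in other settings, to -0.13 after rescaling to TPM.

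Lists of growth and metabolism genes were tested next in B-ALL against wt proB. Of 49 MYC targets tested, 25 rose, 2 fell and 22 did not pass (40 and 2 adjusted over the list alone), at a median of 1.11 (adjusted p = 6.39e-12, and adjusted p = 0.498 with an estimated correlation). The nucleolar genes Mybbp1a (1.94, 104 ± 20.2 against 26.1 ± 1.67 FPKM) and Rrp12 (1.70) were among them, whereas Sord (-2.63) and the phosphatase gene Dusp2 (-2.01) fell. Of 18 glycolysis genes 9 rose and 0 fell (13 and 0 adjusted over the list alone), at a median of 0.95 (adjusted p = 3.33e-06, and adjusted p = 0.440 with an estimated correlation). Among them were enolase Eno1 at 1723 ± 333 against 406 ± 26.0 FPKM (2.07) and the pyruvate dehydrogenase kinase gene Pdk1 (1.78). Of 21 folate genes 7 rose and 0 fell (7 and 0 adjusted over the list alone), at a median of 0.73 (adjusted p = 0.000865, and adjusted p = 0.491 with an estimated correlation). They included Shmt2 and the reduced folate carrier Slc19a1 at 71.0 ± 8.83 against 17.2 ± 1.97 FPKM (1.98, adjusted p = 0.0123). Of 20 serine and nucleotide synthesis genes 5 rose and 0 fell (6 and 0 adjusted over the list alone), at a median of 0.70 (adjusted p = 0.000550, and adjusted p = 0.561 with an estimated correlation). The purine enzyme Ppat (1.46) and the pyrimidine enzyme Cad (1.35) were among them. Of 40 cell cycle genes only Cenpf passed, and it fell (-1.06, 0 and 0 adjusted over the list alone), and the list did not pass (median -0.19, adjusted p = 0.332), although it did after quantile normalization (-0.30, adjusted p = 0.0237).

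Of the B cell lists, genes activated by PAX5, genes activated by EBF1 and mature B cell genes passed as lower. Of 20 genes activated by PAX5, 10 fell and 0 rose (15 and 0 adjusted over the list alone), at a median of -2.15 (adjusted p = 1.43e-06, and adjusted p = 0.466 with an estimated correlation). Among them were the B cell receptor regulator Cd72, from 626 ± 5.18 to 29.6 ± 30.1 FPKM (-4.80), and the transcription factor Lef1, from 361 ± 84.3 to 45.0 ± 33.5 (-3.20). Of 21 genes activated by EBF1, 5 fell and 0 rose (5 and 0 adjusted over the list alone), at a median of -0.58 (adjusted p = 0.0400, and adjusted p = 0.636 with an estimated correlation). They included Fcrla and the costimulatory receptor gene Cd40 (-2.31). The mature B cell list fell by its median of -1.91 (adjusted p = 0.0241, and adjusted p = 0.636 with an estimated correlation). Only Ms4a1, which encodes CD20, passed among its 13 members (2.67 ± 2.32 against 78.8 ± 34.4 FPKM, 1 adjusted over the list alone). Of 16 genes repressed by PAX5, 3 rose and 4 fell (4 and 6 adjusted over the list alone, adjusted p = 0.920). The rises included the cell surface gene Emb (3.10, 120 ± 30.8 against 12.8 ± 0.996) and the T cell adaptor gene Grap2 (1.55), and the falls included the Fc receptor chain Fcer1g (-3.25).

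The lists of stress genes, myeloid markers and interferon-stimulated genes also passed as lower in B-ALL. All 13 stress genes tested fell (13 adjusted over the list alone), at a median of -2.96 (adjusted p = 7.39e-12, and adjusted p = 0.0247 with an estimated correlation). They included Fos and the early growth response gene Egr1 (-5.11). Of 20 myeloid markers 11 fell and 0 rose (11 and 0 adjusted over the list alone), at a median of -1.14 (adjusted p = 1.18e-05, and adjusted p = 0.491 with an estimated correlation). They included Siglech, with 132 and 77.3 FPKM in the wt proB libraries, and Ngp, with 144 and 213. Interferon-stimulated genes had 5 falls and 0 rises among 18 (6 and 0 adjusted over the list alone), at a median of -0.81 (adjusted p = 0.0207, and adjusted p = 0.636 with an estimated correlation). Among them were Bst2, from 240 ± 59.8 to 74.9 ± 22.7 FPKM (-1.68), and Ifi44 (-1.98). The wt proB libraries with the higher interferon values are those that held these myeloid markers. The other lists did not pass, at adjusted p from 0.0695 to 0.746. Genes often mutated in B-ALL passed as lower without mouse 713 (-0.41, adjusted p = 0.0499) or wt proB library 1 (-0.47, adjusted p = 0.0123), recombination genes without wt proB library 2 (-0.71, adjusted p = 0.0354), and red cell markers as higher without mouse 686 (1.91, adjusted p = 0.0166). Of 13 T cell markers 4 rose and 1 fell (4 and 2 adjusted over the list alone). The kinase gene Lck (1.84, 194 ± 107 against 47.1 ± 3.10) and Cd3e (1.52) were higher and Cd4 (-1.78) lower. Of 11 V(D)J recombination genes 1 rose and 4 fell (2 and 5 adjusted over the list alone). Xrcc5, a subunit of Ku, was higher (1.79) and the polymerase gene Polm (-3.87) and the ligase gene Lig4 (-2.44) lower. Of 9 progenitor genes Tal1 rose (1.41) and 3 fell, among them Meis1 (-2.66) and Cd7 (1 and 3 adjusted over the list alone). Of 20 genes often mutated in B-ALL, 5 fell and 0 rose (5 and 0 adjusted over the list alone), with Btg1 (-2.62) and the retinoblastoma gene Rb1 (-2.07) among them. Btg1 had 8.49 and 32.2 FPKM in libraries 1 and 2 of mouse 686 and 85.6 and 220 in mouse 713. It did not pass when only library 2 of each mouse was used (-2.05, adjusted p = 0.0937).

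The remaining lists had few members past the test in B-ALL against wt proB. Of 13 STAT5 targets 3 fell and 0 rose (3 and 1 adjusted over the list alone), with the survival gene Bcl2l1 (-1.81) and the cyclin gene Ccnd3 (-1.66) among the falls. The list's median was 0.00 and its mean 0.14, while the test pointed down (adjusted p = 0.746). Of 11 genes of IL-7 signalling only the kinase gene Jak2 fell (-0.77, adjusted p = 0.0475, 0 adjusted over the list alone), and it lost its call in 16 of 28 other settings, among them without any 1 of the dHet proB libraries. Of 10 genes of the MYC network Mycl (-2.44) and the MYC antagonist Mxd1 (-1.29) fell (2 adjusted over the list alone). The natural cytotoxicity receptor gene Ncr1 fell among 6 NK cell markers (-0.70, 1 adjusted over the list alone), and the plasma cell gene Mzb1 rose among 4 (0.96, 1 adjusted over the list alone). The stromal list had Serpinf1 higher (2.30) and the endothelial cadherin Cdh5 lower (-3.02) among 6 (1 and 2 adjusted over the list alone), while none of 6 red cell and megakaryocyte markers passed (0 adjusted over the list alone). With only library 2 of each mouse Jak2 (adjusted p = 0.0741), Cenpf (adjusted p = 0.0501) and Ncr1 (adjusted p = 0.0742) did not pass. With the mouse as a random effect Btg1 (adjusted p = 0.173), Jak2 (adjusted p = 0.0531), Cenpf (adjusted p = 0.0828) and Ncr1 (adjusted p = 0.146) did not pass. With fry the serine and nucleotide (adjusted p = 0.108), EBF1 (adjusted p = 0.0844), mature B cell (adjusted p = 0.117) and interferon lists (adjusted p = 0.154) did not pass, while the MYC network, progenitor, recombination, often mutated and stromal lists passed as lower.

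The number of genes called in B-ALL against wt proB rested on both wt proB libraries and on mouse 686, with 123 higher and 152 lower without wt proB library 1, 61 and 134 without library 2 and 373 and 682 without mouse 686, while rescaling to TPM gave 529 and 1695 and moved the median of all genes by -0.20, so that 23.8% instead of 44.9% of the called genes were higher. Of the 54 named genes that passed, 13 kept the call in every setting that left out a library or mouse and tested them (Rnase12, Crisp1, Myl10, Pdk1, Siglech, Cd7, Fos, Egr1, Lig4, Meis1, Mycl, Ms4a1 and Cdh5, the last not tested without either wt proB library) and 25 more, among them Shmt2, Slc19a1, Mybbp1a, Emb, Lef1, Cd72 and Ngp, lost the call only when a wt proB library was left out; Ebf1 lost it without wt proB library 2 (-0.75) and without mouse 686, the EBF1 list without any of 5 libraries or mice (to a median of -0.32 without wt proB library 1), the mature B cell list without any of 3 and the interferon list without wt proB library 2 or mouse 686 (-0.44). Besides either wt proB library, Fcrla, Mzb1 and Xrcc5 lost the call without mouse 686, Cd40, Ppat, Rrp12, Sord and Cad without mouse 686 or 760, and Lck without mouse 713. Cad also lost it without library 1 of mouse 713, and Cd3e and Ifi44 without mouse 686, mouse 713 or dHet proB library 1. Cenpf lost it in 8 and Btg1 in 9 of 14 settings, and Ncr1 without mouse 686 or library 1 of mouse 713.

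Next, leukemic cells were compared with the pre-leukemic dHet proB cells. Ly86, which encodes a partner of a toll-like receptor homologue, had 186 ± 53.7 FPKM in B-ALL and was listed at 0 in every dHet proB library (adjusted p = 8.65e-06). Cd74, the invariant chain of MHC class II, was higher at 1735 ± 2435 against 7.84 ± 9.45 FPKM (log2 6.94, adjusted p = 0.00638), and the class II gene H2-Ab1 at 370 ± 382 against 3.24 ± 1.91 (6.04, adjusted p = 0.00146). Jchain, the joining chain of secreted antibodies, rose by 6.40 (156 ± 112 against 0.357 ± 0.348, adjusted p = 0.00194), the transferrin gene Trf by 6.39 (adjusted p = 0.00640) and Rnase12 by 6.33 (1278 ± 237 against 21.6 ± 23.6, adjusted p = 0.000918). The largest falls were in the G protein subunit Gng4, from 70.6 ± 40.8 to 0.723 ± 1.01 (-5.36, adjusted p = 0.000750), and in the tryptophan catabolism gene Kynu, from 81.2 ± 56.8 to 1.06 ± 0.499 (-4.99). Bcar3 fell from 46.0 ± 19.9 to 0.951 ± 1.41 (-4.74), followed by the membrane linker radixin Rdx (-4.55), Lpcat2 (-4.52) and Fxyd6 (-4.37). In total 1614 genes were higher and 1218 lower in B-ALL, of which 939 and 602 changed by 2-fold or more.

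Shmt2 was again higher, at 226 ± 44.8 against 58.9 ± 26.9 FPKM in dHet proB (log2 2.0, adjusted p = 0.00462). Pax5 (-0.95, adjusted p = 0.0214), Ebf1 (-0.83, adjusted p = 0.0374) and Rag1 (-1.14, adjusted p = 0.0265) were lower in B-ALL. Pax5 lost its call without dHet proB library 1 or mouse 760, and Ebf1 without any dHet proB library, mouse 686 or mouse 760. Rag1 lost it without dHet proB library 1 or 3, mouse 686 or mouse 760. Myc did not pass (2.68, adjusted p = 0.0886), with 9.39, 42.3 and 290 FPKM in dHet proB libraries 1, 2 and 3 against 203 to 445 in the B-ALL libraries. It passed in 5 of 29 other settings, among them without dHet proB library 3 (3.94, adjusted p = 0.00726). Rag2 (0.38), Il7r (-0.23) and Mthfd2 (0.69, adjusted p = 0.161) did not pass, although Mthfd2 did without dHet proB library 2 (1.07, adjusted p = 0.0191).

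The same growth and metabolism lists passed as higher in B-ALL against dHet proB. Of 49 MYC targets 42 rose and 1 fell (45 and 1 adjusted over the list alone), at a median of 1.29 (adjusted p = 1.78e-12, and adjusted p = 0.491 with an estimated correlation). The spermidine synthase gene Srm (2.67, adjusted p = 0.0362) and Mybbp1a (2.27, adjusted p = 0.00293) rose and Sord fell (-3.35). Srm lost its call without dHet proB library 2, a wt proB library, mouse 686 or mouse 760, and moved to 1.72 without dHet proB library 1. Of 21 folate genes 8 rose and 0 fell (10 and 1 adjusted over the list alone), at a median of 0.69 (adjusted p = 0.00384, and adjusted p = 0.498 with an estimated correlation). The purine synthesis enzyme Gart was among them (2.08, adjusted p = 0.00544). Of 20 serine and nucleotide genes 11 rose and 0 fell (12 and 0 adjusted over the list alone), at a median of 0.95 (adjusted p = 0.000271, and adjusted p = 0.548 with an estimated correlation). Among them were Phgdh, the entry enzyme of serine synthesis, at 411 ± 65.5 against 92.7 ± 65.1 FPKM (2.33) and Cad (2.17). Of 18 glycolysis genes 11 rose and 0 fell (13 and 0 adjusted over the list alone), at a median of 1.02 (adjusted p = 2.28e-05, and adjusted p = 0.466 with an estimated correlation). Among them were the glucose transporter gene Slc2a3 (2.30) and Ldha (1.64). None of 40 cell cycle genes passed (0 adjusted over the list alone, median -0.06, adjusted p = 0.523), but the list passed as lower without dHet proB library 3 (-0.38, adjusted p = 0.000236). These lists were not uniform among the dHet proB libraries. All 40 cell cycle genes were lower in library 3 than in libraries 1 and 2.

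Genes of B cell identity moved in both directions. Of 20 genes activated by PAX5, 11 fell and 1 rose (13 and 1 adjusted over the list alone), at a median of -1.43 (adjusted p = 1.09e-06, and adjusted p = 0.466 with an estimated correlation). Lef1 (-3.62, 45.0 ± 33.5 against 481 ± 87.5 FPKM) and Bcar3 were lower and the adaptor gene Nedd9 was higher (1.13, adjusted p = 0.0294). Nedd9 lost its call when any mouse or either wt proB library was left out. Of 16 genes repressed by PAX5, 6 rose and 1 fell (6 and 3 adjusted over the list alone, adjusted p = 0.258). Emb (4.02, 120 ± 30.8 against 7.31 ± 4.33) and the cytokine receptor Flt3 (3.80, 44.7 ± 30.8 against 1.81 ± 1.41) were higher and the chemokine gene Ccl9 was lower (-4.11). Of 21 genes activated by EBF1, 2 rose and 2 fell (2 and 2 adjusted over the list alone, adjusted p = 0.399). The kinase gene Blk (2.39) and Myl4 (1.69) were higher and Foxo1 (-1.77) and the tetraspanin Cd53 (-1.11) lower. Mature B cell genes were higher, with 8 rises and 0 falls among 13 (10 and 1 adjusted over the list alone), at a median of 1.86 (adjusted p = 0.00239, and adjusted p = 0.548 with an estimated correlation). Cd74 and H2-Ab1 were among them. Cd74 had 4599 and 4482 FPKM in mouse 713 against 484 and 481 in mouse 686 and 191 and 171 in mouse 760. Without mouse 713 the list's median was 1.21. Of 20 genes often mutated in B-ALL, 5 fell and 1 rose (6 and 2 adjusted over the list alone), at a median of -0.45 (adjusted p = 0.0110, and adjusted p = 0.397 with an estimated correlation). The cell cycle inhibitor Cdkn1a (-2.97) and Rb1 (-1.68) were lower and Etv6 was higher (0.73), and the median was -0.71 without mouse 713. Cdkn1a lost its call without any dHet proB library, either wt proB library, mouse 686 or mouse 760, and Etv6 lost it in 17 of 29 settings. With the mouse as a random effect neither Rb1 (adjusted p = 0.0525) nor the list (adjusted p = 0.0779) passed.

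Several markers of cell types that can reside in a lymph node were higher in B-ALL than in the cultured cells. Of 13 T cell markers 8 rose and 0 fell (8 and 0 adjusted over the list alone), at a median of 1.5 (adjusted p = 0.000200, and adjusted p = 0.397 with an estimated correlation). Cd3g stood at 3.77 ± 1.80 against 0.0816 ± 0.141 FPKM (2.06) and Cd3e at 3.53 ± 1.93 where dHet proB was listed at 0. Of 20 myeloid markers 5 rose and 0 fell (5 and 0 adjusted over the list alone), at a median of 0.78 (adjusted p = 0.00826, and adjusted p = 0.621 with an estimated correlation). The rises included the oxidase gene Cybb (2.65) and C1qb, at 6.72 ± 4.95 where dHet proB was listed at 0. The myeloid list lost its call without mouse 686 (median 0.10) and had a median of 1.52 without mouse 760. With fry it did not pass (adjusted p = 0.0776), while the NK cell, red cell and plasma cell lists passed as higher. Of 6 NK cell markers 3 rose (4 adjusted over the list alone, adjusted p = 0.115), among them Nkg7 (3.36) and Gzma, at 2.88 ± 3.14 where dHet proB was listed at 0. Both lost their call without any 1 of the dHet proB libraries, and Gzma in 14 of 28 settings. Gzma had 1.73, 6.44 and 0.475 FPKM in mice 686, 713 and 760. Of 6 red cell markers the globin genes Hba-a1, at 107 ± 125, and Hbb-b1, at 79.8 ± 101, rose where dHet proB was listed at 0 (2 adjusted over the list alone, adjusted p = 0.0695). Plasma cell genes had 2 rises among 4, Jchain and Derl3 (2.32, 2 adjusted over the list alone, adjusted p = 0.0556). The stromal list had 2 among 6, Serpinf1 (3.67) and Vcam1, at 1.28 ± 0.884 where dHet proB was listed at 0 (2 adjusted over the list alone, adjusted p = 0.599). The NK cell list passed without mouse 760 (median 1.32, adjusted p = 0.0238). Without mouse 686 the red cell (2.64, adjusted p = 0.00147), plasma cell (1.54, adjusted p = 0.0470) and interferon lists (0.53, adjusted p = 0.00809) passed as higher. The plasma cell list also passed without mouse 713 (1.57), either wt proB library or dHet proB library 3 (1.96), and the red cell list without wt proB library 2 (2.96).

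Stress genes fell by a median of -0.51 (adjusted p = 0.0215, and adjusted p = 0.397 with an estimated correlation), with 3 of 13 members past the test (3 adjusted over the list alone). The AP-1 gene Jund (-3.04) and Btg2 (-1.68) were among these. The median was -0.92 without either wt proB library, where only the set of genes tested changed and not their log2 fold changes. Jund had 4.51 and 38.1 FPKM in libraries 1 and 2 of mouse 686, 9.59 and 61.4 in mouse 713 and 9.29 and 16.4 in mouse 760, against 105 to 193 in dHet proB. Foxo1 showed the same kind of difference, at 4.51 and 12.9, 12 and 28, and 7.90 and 12.4. Of the 156 genes that were lower in library 1 of mice 686 and 713, 82 (52.6%) were called lower in B-ALL than in dHet proB, against 11% of all tested genes. Against wt proB 14 of the 156 (8.97%) were called lower, against 10% of all tested genes. In dHet proB against wt proB 21 of the 156 were called higher, against 242 of all 11110 tested genes. There 2 (1.28%) were called lower, against 6.50% of all tested genes. Of the 82, 23 were called when only library 2 of each mouse was used. Jund and Foxo1 kept their calls in that setting, Etv6 did not (0.57, adjusted p = 0.0838), and 1470 genes were higher and 1025 lower. With the mouse as a random effect Jund (adjusted p = 0.214), Foxo1 (adjusted p = 0.145), Etv6 (adjusted p = 0.135) and Mxd4 (adjusted p = 0.290) did not pass.

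The other lists did not pass in B-ALL against dHet proB. Of 11 genes of IL-7 signalling the common gamma chain Il2rg rose (0.97, 294 ± 58.9 against 148 ± 6.17 FPKM). The 3 that fell included the receptor gene Kit (-2.32, 16.9 ± 9.45 against 81.9 ± 31.2) and Jak2 (-1.0, 1 and 3 adjusted over the list alone, adjusted p = 0.347). The dHet proB cells had been taken as c-Kit+ cells, and the part of that selection in the Kit difference was not tested. Bcl2l1 alone fell among 13 STAT5 targets (-1.89, 1 adjusted over the list alone, adjusted p = 0.340). The MYC antagonists Mxd4 (-1.43) and Mxd1 (-1.38) fell among 10 MYC network genes (2 adjusted over the list alone, adjusted p = 0.154). Of 9 progenitor genes 2 rose and 2 fell (2 and 2 adjusted over the list alone). Tal1 was higher (1.24), as was Cd7, at 1.60 ± 0.294 where dHet proB was listed at 0, and Sox4 (-1.5) and Meis1 (-0.84) were lower. The progenitor list's median was 0.11 while the test pointed down (adjusted p = 0.674). Of 11 recombination genes Xrcc5 rose (1.34) and 4 fell, including Lig4 (-1.90) and the Artemis gene Dclre1c (-1.18, 2 and 4 adjusted over the list alone, adjusted p = 0.338). The interferon genes Oasl1 (2.95) and Oas1a (2.71) were among 3 rises in 18 (3 adjusted over the list alone, adjusted p = 0.258).

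The counts for B-ALL against dHet proB fell to 811 higher and 582 lower without dHet proB library 1 and to 810 and 585 without mouse 686, and rescaling to TPM, which moved the median of all genes by -0.18, turned the balance, with 38.8% instead of 57.0% of the called genes higher, as did quantile normalization with 46.3%. Of the 64 named genes that passed, 46 did so whichever library or mouse was left out, among them Rnase12, Ly86, Cd74, Shmt2, Mybbp1a, Phgdh, Lef1, Emb, Flt3, Rb1 and Lig4, while 16 lost the call without dHet proB library 1 and 12 without mouse 686. Xrcc5 lost it without dHet proB library 1 or 3 or mouse 686, Cybb without dHet proB library 1 or 2, mouse 686 or mouse 713, and Rdx without dHet proB library 1 or 2 or mouse 760. Hbb-b1 and Vcam1 lost it without any 1 of the dHet proB libraries, and besides without mouse 760 and mouse 686. Btg2 and Mxd4 lost it without dHet proB library 1 or mouse 686, and Kit and Meis1 without dHet proB library 1.

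**Figure D2:**
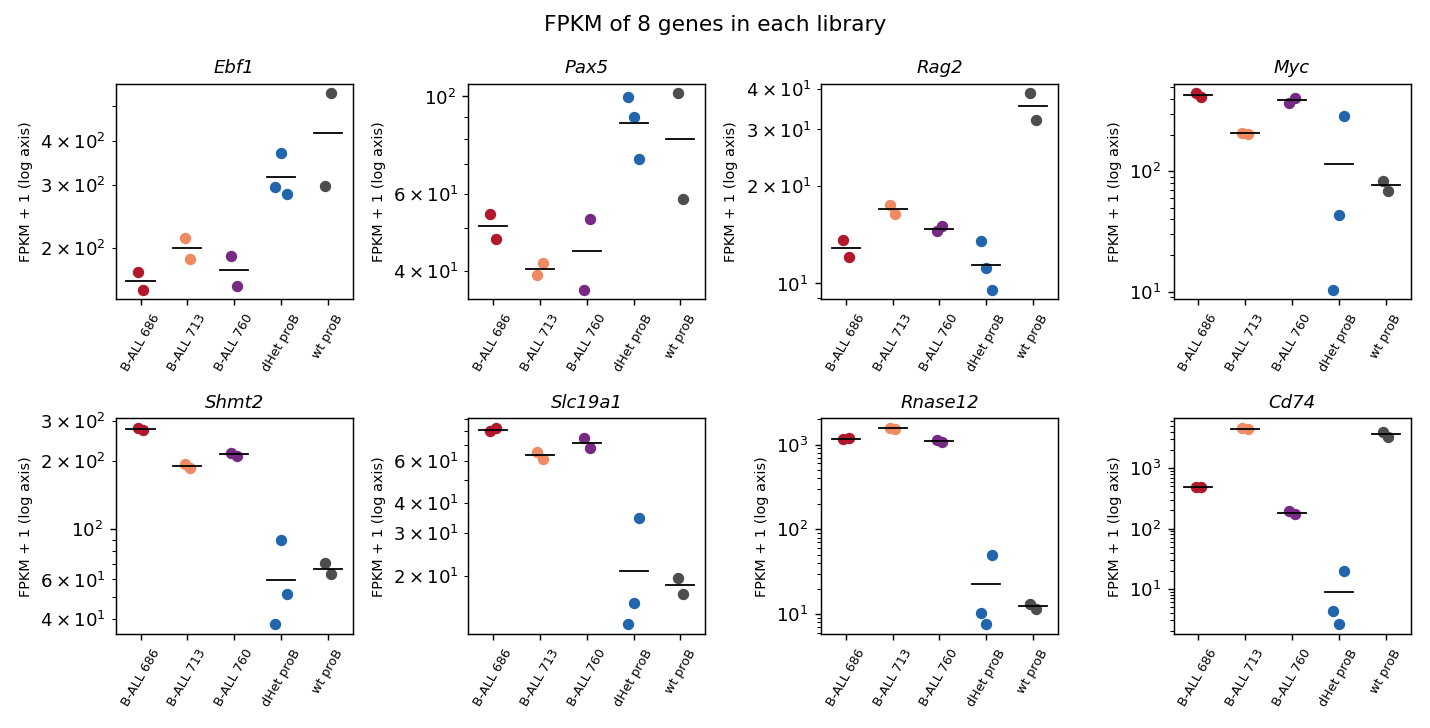
FPKM + 1 (vertical log axis) of Ebf1, Pax5, Rag2, Myc, Shmt2, Slc19a1, Rnase12 and Cd74, with 1 point per library. The B-ALL mice are shown in separate columns beside dHet proB and wt proB, colours mark the columns and bars give the mean of each. Rnase12 reached 1278 FPKM on average in B-ALL against 21.6 in dHet proB and 11.3 in wt proB, whereas Myc in B-ALL overlapped with dHet proB, through 290 FPKM in library 3, and lay above wt proB.

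The genes that set leukemic cells apart from both kinds of proB cells were then counted. Rnase12, Shmt2, Mybbp1a, Emb and Tal1 were higher in B-ALL than in each proB group, and Lef1, Lig4, Rb1 and Bcl2l1 were lower. In total 653 genes were higher than in both groups and 446 lower. Independent lists of these sizes would share 131 and 122. Simulated unchanged groups with the same B-ALL units shared 0 and 0, but with no changed genes few or none are called in them. That simulation cannot measure the overlap that shared units create when many genes are called. Only 6 and 33 genes were called in opposite directions, and part of the excess may come from the B-ALL units that the comparisons share. The list of MYC targets contributed 24 genes higher and 1 lower, folate genes 7 and 0, glycolysis genes 6 and 0, and serine and nucleotide genes 5 and 0. T cell markers contributed 4 and 0, genes repressed by PAX5 3 and 0 and genes activated by PAX5 0 and 9. Genes often mutated in B-ALL and stress genes each contributed 0 higher and 3 lower, and cell cycle genes 0 and 0. The counts were 91 and 89 without wt proB library 1, 52 and 66 without library 2, and 251 and 192 without mouse 686, and 245 were lower without dHet proB library 1. They were 347 and 750 after rescaling to TPM.

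The pre-leukemic dHet proB cells were compared with wt proB cells, a comparison in which the Rag2 genotype, the tissue and the culture also change. Here too the wt proB libraries held transcripts of other cell types, described below, whose part in the falls was not tested. Cd74, H2-Ab1 and H2-Aa, genes of MHC class II, were among the 6 largest falls. Cd74 fell from 3618 ± 475 FPKM in wt proB to 7.84 ± 9.45 (log2 -9.23, adjusted p = 0.00408), and H2-Ab1 from 1028 ± 26.8 to 3.24 ± 1.91 (-8.02, adjusted p = 0.000643). H2-Aa was listed at 0 in dHet proB against 358 ± 99.8 (adjusted p = 0.00210). The signalling adaptor Tyrobp fell from 279 ± 98.8 to 0.871 ± 0.701 (-7.26, adjusted p = 0.000233) and Ngp from 179 ± 49.0 to 0.702 ± 0.747 (-6.79). Cd7 was listed at 0 against 140 ± 70.7 (adjusted p = 2.91e-05). The largest rises were in Gng4, at 70.6 ± 40.8 against 0.190 ± 0.00832 (5.74, adjusted p = 0.000772), and in the placental growth factor gene Pgf, at 95.3 ± 71.2 against 0.562 ± 0.197 (5.69). Ifitm1 rose to 272 ± 230 from 4.43 ± 1.96 (5.35) and the metallothionein Mt2 to 25.1 ± 24.1 from 0.0451 ± 0.0639 (4.26), followed by the phosphodiesterase Pde8a (4.09) and Kynu (3.84). In total 242 genes were higher and 722 lower in dHet proB, of which 162 and 653 changed by 2-fold or more.

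Rag2 was lower in dHet proB at 10.4 ± 2.0 against 34.5 ± 4.72 FPKM (-1.64, adjusted p = 0.00266). Ebf1 (-0.36), Pax5 (0.17), Rag1 (0.05), Myc (-0.58), Il7r (0.59), Mthfd2 (-0.62) and Shmt2 (-0.25) did not pass. Several of these values changed sign when a library was left out: Ebf1 was 0.0771 and Pax5 -0.23 without wt proB library 2, Myc 0.56 and Shmt2 0.0281 without dHet proB library 1, and Rag1 -0.16 without dHet proB library 3.

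Between dHet proB and wt proB, 7 of the 23 lists passed, all as lower in dHet proB. How far transcripts of other cell types in the wt proB libraries account for these falls was not tested. Of 20 myeloid markers 14 fell and 0 rose (17 and 0 adjusted over the list alone), at a median of -2.96 (adjusted p = 1.78e-12, and adjusted p = 0.397 with an estimated correlation). Ngp and Siglech were among them, the latter listed at 0 in dHet proB against 105 ± 38.8. Of 13 stress genes 11 fell (12 adjusted over the list alone), at a median of -2.61 (adjusted p = 4.36e-11, and adjusted p = 0.0247 with an estimated correlation). Among them were Fos (-4.89) and the phosphatase gene Dusp1 (-4.00). Of 13 mature B cell genes 8 fell and 0 rose (9 and 0 adjusted over the list alone), at a median of -3.38 (adjusted p = 4.64e-07, and adjusted p = 0.466 with an estimated correlation). Interferon-stimulated genes had 5 falls among 18 (7 adjusted over the list alone), at a median of -1.16 (adjusted p = 5.79e-05, and adjusted p = 0.498 with an estimated correlation). Bst2 stood at 34.9 ± 3.32 against 240 ± 59.8 (-2.73), and Ifi44 was listed at 0 in dHet proB. T cell markers had 3 falls among 13 (4 adjusted over the list alone), at a median of -0.79 (adjusted p = 0.00135, and adjusted p = 0.397 with an estimated correlation). Among them were Cd4, listed at 0 against 5.14 ± 1.76, and Cd8b1, listed at 0 against 2.89 ± 1.54. NK cell markers had 2 falls among 6 (4 adjusted over the list alone), at a median of -1.54 (adjusted p = 0.0139, and adjusted p = 0.466 with an estimated correlation). Prf1 was lower (-1.33) and Ncr1 was listed at 0 in dHet proB. Stromal markers had 2 falls among 6, Cdh5 (-3.06) and Vcam1, listed at 0 against 3.30 ± 0.932 (2 adjusted over the list alone), at a median of -0.97 (adjusted p = 0.0451, and adjusted p = 0.584 with an estimated correlation).

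No list of growth or metabolism passed between dHet proB and wt proB. MYC targets had 1 fall among 49, Dusp2 (-1.48, 0 adjusted over the list alone, median -0.22, adjusted p = 0.421), and passed as lower without dHet proB library 3 (-0.37, adjusted p = 0.0125). Glycolysis had 1 fall among 18, Slc2a3 (-1.43, 1 and 1 adjusted over the list alone), with a median of -0.02 while the test pointed up (adjusted p = 0.572). Folate, serine and nucleotide, and cell cycle genes had no member past the test (0 adjusted over each list alone). Their medians were -0.03, -0.19 and -0.13 and their adjusted p 0.777, 0.599 and 0.599 with limma camera, and for folate the test pointed up. The cell cycle list had a median of 0.14 and passed (adjusted p = 0.00831) without dHet proB library 3, and a median of -0.47 (adjusted p = 0.000226) without library 2. Genes repressed by PAX5 passed as lower without dHet proB library 1 (-0.86, adjusted p = 0.0316) or 3 (-0.81, adjusted p = 0.0286), and IL-7 signalling genes as higher without library 2 (0.33, adjusted p = 0.0289). Of 20 genes activated by PAX5 only Bcar3 passed, and it rose (2.54, 2 and 1 adjusted over the list alone, median 0.09, mean -0.18, adjusted p = 0.972). The 16 genes repressed by PAX5 had Ccl9 higher (3.71) and 3 lower, among them the chemokine receptor Ccr2 (-3.01, 1 and 4 adjusted over the list alone, adjusted p = 0.111). Of 21 genes activated by EBF1 Cd53 rose (0.84) and 5 fell, including Cd40 (-3.01) and Myl4 (-2.27, 1 and 5 adjusted over the list alone, adjusted p = 0.197). Of 9 progenitor genes Sox4 rose (1.10) and 3 fell, including Meis1 (-1.82, 2 and 4 adjusted over the list alone, adjusted p = 0.242). Of 11 recombination genes Polm (-3.66) and Rag2 fell (2 adjusted over the list alone, adjusted p = 0.320). Kit rose among IL-7 signalling genes (3.15, 1 adjusted over the list alone, adjusted p = 0.143), in dHet proB cells that had been taken as c-Kit+ cells. Socs2 rose among STAT5 targets (3.28, 1 adjusted over the list alone, adjusted p = 0.674). Socs2 had 85.9, 146 and 817 FPKM in dHet proB libraries 1, 2 and 3 against 22 and 21 in wt proB. Mycl fell in the MYC network (-1.90, 1 adjusted over the list alone), where the median was -0.03 and the test pointed up (adjusted p = 0.884). Cdkn2a, a tumour suppressor gene, rose among genes often mutated in B-ALL (3.50, 0 adjusted over the list alone, median -0.05, mean 0.12, adjusted p = 0.777). Jchain fell among plasma cell genes (-6.72, 1 and 2 adjusted over the list alone, adjusted p = 0.332), and no red cell marker passed (0 adjusted over the list alone, adjusted p = 0.258). With fry the progenitor and plasma cell lists passed as lower. With the mouse as a random effect Pde8a (adjusted p = 0.0768), Sox4 (adjusted p = 0.251) and the NK cell list (adjusted p = 0.0784) did not pass.

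The counts for dHet proB against wt proB fell to 13 higher and 63 lower without wt proB library 1 and to 20 and 95 without library 2, 129 were higher without dHet proB library 1, and quantile normalization raised the share of called genes that were higher from 25.1% to 45.4% with 505 higher. Of the 40 named genes that passed, 11 kept the call in every setting that left out a library or mouse and tested them (Gng4, Pde8a, H2-Ab1, Tyrobp, Cd7, Siglech, Fos, Bst2, Cd4, Ncr1 and Cdh5, the last 2 not tested without either wt proB library) and 18 more only lost the call when a wt proB library was left out, while the NK cell list lost its call without dHet proB library 2 or wt proB library 1 and the stromal list without any of 4 libraries or mice, with a median of -0.63 without wt proB library 1 and -1.60 without dHet proB library 1. Besides either wt proB library, Bcar3, Cd53, Ifi44, Ifitm1, Polm and Ccl9 lost the call without dHet proB library 1 or 3, Cdkn2a without 1 or 2, Cd40 without 1 and Socs2 without 2. Dusp2 and Prf1 lost it without any 1 of these libraries, and some also without a mouse: Ccl9 without mouse 686, Dusp2 without mouse 760 and Socs2 without either. B-ALL and dHet proB shared 64 genes higher and 447 lower than in wt proB, where independent lists would share 19.7 and 72.3. Simulated unchanged groups shared 0.01 and 0.01 on average, but with no changed genes few or none are called in them. Part of the excess may come from the shared wt proB libraries, and that simulation cannot measure how much.

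**Figure D3:**
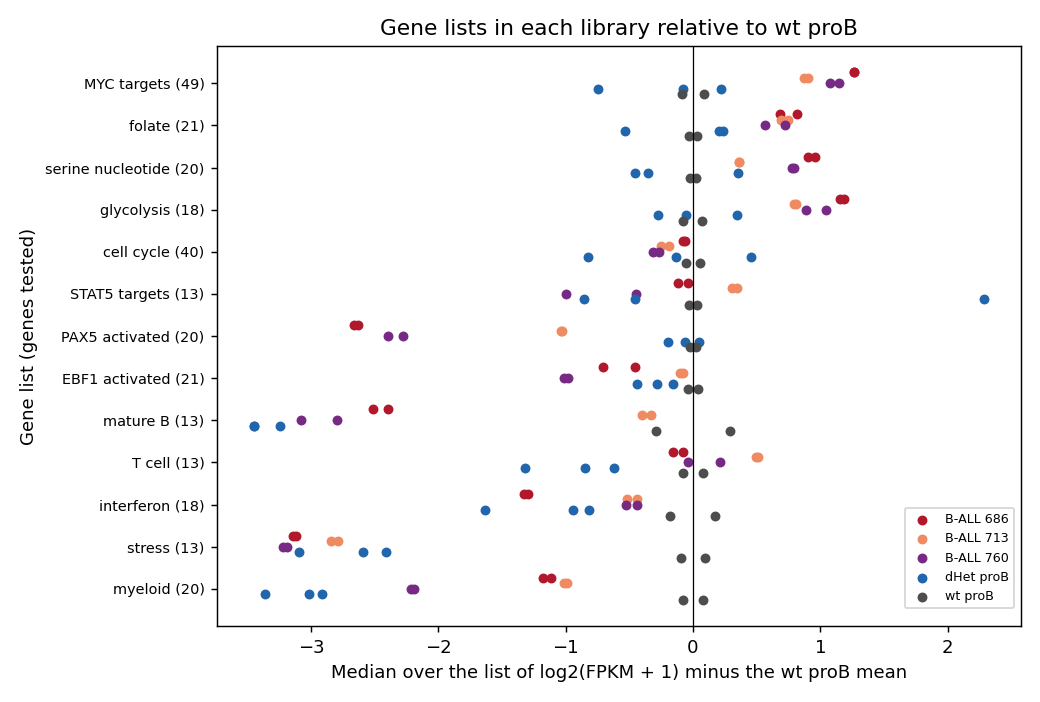
Median over each of 13 gene lists of log2(FPKM + 1) minus the wt proB mean (horizontal axis), with 1 point per library and the colours showing the groups. The number of genes tested is given beside each list. MYC targets lie between 0.87 and 1.27 in the B-ALL libraries and at -0.75, -0.0764 and 0.22 in dHet proB, and STAT5 targets lie at 2.29 in dHet proB library 3.

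Finally, the 3 leukemic mice were compared with each other, against the spread between libraries. Mouse 713 carried far more of the adhesion gene Cd2, at 403 FPKM against 6.59 in mouse 686 and 1.64 in mouse 760 (limma adjusted p = 1.40e-05). It also carried more of the fatty acid transporter Cd36 (136 against 0.494 and 0.149) and of the heparan sulfate enzyme Hs3st2 (28.3 against 0.00628 in mouse 686 and a listing at 0 in mouse 760). Mouse 760 had the epithelial adhesion gene Epcam at 67.6 against 2.88 and 0.295 (limma adjusted p = 1.19e-07). It had Krtcap3 at 18.6 against 0.326 and 0.306 and the Fc receptor-like gene Fcrl6 at 24.5 against 0.728 and 0.799. Mouse 686 had Fam92a at 26.5 against 0.222 and 0.0298 (limma adjusted p = 1.17e-06), as well as Rdx at 31.3 against 0.654 and 0.112 and Ngp at 17.3 against 0.503 and 0.208. All 9 kept their calls in every setting that left out a library and tested them, and Hs3st2 was not tested without either library of mouse 713. That is a weak check, since the genes were picked for the largest excess in the same data and the libraries of a mouse are alike.

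In total 2513 of 11293 genes differed between the mice. Pairwise, 1754 differed between mice 686 and 713, 794 between 686 and 760 and 2448 between 713 and 760. Lists of B cell genes were highest in mouse 713. Of 20 genes activated by PAX5, 16 differed (17 adjusted over the list alone), 13 of these highest in mouse 713. The same held for 12 of 13 EBF1-activated genes that differed among 21 (16 adjusted over the list alone) and 10 of 11 mature B cell genes that differed among 13 (11 adjusted over the list alone). Of 18 interferon genes 12 differed (12 adjusted over the list alone), 9 of them highest in mouse 713. Of 20 myeloid markers 15 differed (16 adjusted over the list alone), 8 highest in mouse 686 and 7 in mouse 713. Of 15 T cell markers 12 differed (14 adjusted over the list alone), 5, 3 and 4 of them highest in mice 686, 713 and 760. The red cell gene Hba-a1 had 4.07 and 5.48 FPKM in mouse 686, 218 and 277 in mouse 713 and 63.9 and 75.9 in mouse 760. Few growth genes differed, with 4 of 49 MYC targets (1 adjusted over the list alone), 3 of 18 glycolysis genes (3), 1 of 21 folate genes (1), 2 of 20 serine and nucleotide genes (2) and 0 of 40 cell cycle genes (0). Of the other lists, 7 of 11 IL-7 signalling genes differed, 7 of 16 genes repressed by PAX5, 6 of 7 NK cell, 4 of 6 red cell and 4 of 6 stromal markers (7, 7, 6, 5 and 5 adjusted over the list alone). All 4 red cell and all 4 stromal markers that differed were highest in mouse 713, as were 4 of the 6 NK cell markers. So did 5 of 20 genes often mutated in B-ALL, 4 of 9 progenitor genes and 3 of 11 recombination genes (6, 4 and 4 adjusted over the list alone), and 3 of 13 stress genes, 2 of 10 MYC network genes, 2 of 4 plasma cell genes and 1 of 13 STAT5 targets (3, 2, 2 and 1 adjusted over the list alone). The number of genes that differed was 1344 and 1302 when library 1 or 2 of mouse 713 was left out and 1628 and 1652 for mouse 760. It was 5073 when only the B-ALL libraries were fitted.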

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

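The tests of the scale, of leukemic cells and of sex for dHet proB library 3, of the scale between groups and of markers that pass the filter without wt proB for the wt proB libraries, and of random placement and of Pnp for the neighbouring genes were chosen only after the result was seen. Groups held 2 or 3 units, too few to test single samples as outliers.

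Of the 9 genes named for the mice, 6 lay above both wt proB libraries in 1 leukemic mouse and below both in another. Only pairs of mice that differed at a limma adjusted p under 0.05 were counted. These genes gave 12 such pairs of a gene and 2 mice, and all 11293 tested genes gave 1540. The named genes had been chosen for large differences between the mice. Only the mice were tested against each other, and no single mouse was tested against wt proB. In mice 686, 713 and 760 the log2 differences from wt proB were -3.08, 2.65 and -4.61 for Cd2, -2.50, 4.02 and -2.87 for Cd36 and 0.11, -1.48 and 4.25 for Epcam. They were 0.62, -3.87 and -4.12 for Fam92a, -1.79, -1.74 and 2.08 for Fcrl6 and -1.04, -1.07 and 2.84 for Krtcap3. Cd2 differed by a log2 fold change of -5.73 between mice 686 and 713 (limma adjusted p = 5.22e-05) and of 7.26 between 713 and 760 (adjusted p = 7.52e-06). Cd36 differed by -6.52 (adjusted p = 0.000338) and 6.90 (adjusted p = 0.000164) in the same contrasts. Epcam differed by 1.59 between mice 686 and 713 (adjusted p = 6.80e-05) and by -5.73 between 713 and 760 (adjusted p = 4.11e-08). Fam92a differed by 4.49 between 686 and 713 (adjusted p = 2.11e-06) and by 4.74 between 686 and 760 (adjusted p = 2.65e-06). Fcrl6 differed by -3.87 between 686 and 760 (adjusted p = 4.11e-05) and by -3.81 between 713 and 760 (adjusted p = 1.44e-05), and Krtcap3 by -3.88 (adjusted p = 1.45e-06) and -3.91 (adjusted p = 3.19e-07). Each difference is measured against the spread between libraries.

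dHet proB library 3, titled replicate 3 with a source name that says replicate 2, differed from libraries 1 and 2: its STAT5 targets were higher by a median log2 of 2.69 (10 of 13 above both libraries), with Socs2 at 85.9, 146 and 817 FPKM, Cish at 4.83, 9.44 and 82.4 and Pim1 at 135, 151 and 670, Myc stood at 9.39, 42.3 and 290, and all 40 cell cycle genes were lower, by a median of -1.07. A shift of the whole library would move all genes the same way, whereas STAT5 targets were higher and cell cycle genes lower. It is therefore excluded as the only cause. The median over all tested genes differed by only 0.0207, but the unknown scaling of the values may itself have set that median. Leukemic cells like those of the mice are excluded too as the only source of its Myc, which reached 83.6% of the leukemic level. In this library 9 genes abundant in every leukemic mouse reached a median of 2.94% of their leukemic level (quartiles 0.941% and 4.46%). The highest were Pnp2 at 21.7% and Tmem119 at 14.0%. A small share of such cells, or leukemic cells that lack these transcripts, is not excluded. The sex of the embryo is excluded, since library 1 had Xist as library 3 did (FPKM 11.2 and 15.1, and 0 in library 2). A difference in cytokine exposure or growth of the culture stays open as a hypothesis that no label allows to test.

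The wt proB libraries held transcripts of plasmacytoid dendritic cells and neutrophils, with Siglech at 132 and 77.3 FPKM, Ngp at 144 and 213 and S100a8 at 129 and 82.5, whereas no other library exceeded 1.65 for Siglech and 18.3 for Ngp. Of 21 tested markers in a list of dendritic cell genes written without looking at their values, 16 were higher in both wt proB libraries than in each of the 9 other libraries, where random lists of like level had a median of 5 and a maximum of 14, and among markers that pass the filter without wt proB 7 of 12 were, no more than the maximum of 7 in random lists (2 of 10000 had as many), which by the same bound leaves that version undecided, while 11.6% of all tested genes behaved so against 1.82% by chance. For neutrophils the test is undecided. Of 13 tested markers 11 were higher, which met the bound written beforehand for such cells. Random lists had a median of 4 and a maximum of 12 (1 of 10000 had as many), so the bound against such cells was met too. Only 2 of the markers pass the filter without wt proB, and 1 of these was higher, as in 23.8% of random lists. A scale difference between the groups is not settled. In B-ALL against wt proB the median of all genes differed by -0.0231 in the deposited values, whose scaling is unknown. After rescaling to TPM it differed by -0.22. Both are smaller in size than the median of -1.14 that the myeloid list had in the deposited values. Plasmacytoid dendritic cells among the sorted wt proB cells may be the source of their markers, a hypothesis about a sort whose markers are not given, and neutrophils stay open, as do the tissue, the culture and the genotype, which change with the group and are untested.

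Rnase12, Rnase11, Rnase9, Rnase10 and Pnp2 are neighbours among the 10552 tested genes placed by symbol in the RefSeq gene order of assembly GRCm38.p6. Genes that were not tested or not placed were left out of that order, also for the random placements. All 5 were higher in B-ALL than in both proB groups, at 1278 ± 237, 28.4 ± 18.5, 2.45 ± 1.66, 51.0 ± 58.6 and 210 ± 96.7 FPKM. A run of 5 or more arose in 64 of 10000 random placements of the calls (permutation p = 0.0065), and neighbouring pairs numbered 54 against a mean of 36.7 (permutation p = 0.0025). Of the 624 words of 50 bases in the Rnase12 transcripts of GENCODE M21, 0% occur in Rnase9, Rnase10 or Rnase11. Shared reads of that kind are therefore excluded between Rnase12 and these genes. Sharing among Rnase9, Rnase10 and Rnase11 was not tested. Reads shared with Pnp are excluded as the whole source for Pnp2, since 28.5% of its 1538 words occur in Pnp and Pnp changed against dHet proB by a log2 of 0.57 (upper bound 1.49), below Pnp2 at 3.41 (lower bound 1.93), and against wt proB rose by 1.84 (upper bound 2.87, limma adjusted p = 0.0266), below Pnp2 at 5.46 (lower bound 3.80). A regulatory change shared by these neighbours in leukemic cells is a hypothesis found and tested on the same data, and the tissue and culture that differ between the groups stay open and untested.

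For the number of genes called between B-ALL and dHet proB, 1 of the 10 splits of the 6 units, the real split with 2832 genes, gave as many, and the highest of the others gave 6. With 10 splits a share under 0.05 cannot arise.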

How the results depend on the processing

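The settings that leave out mouse 713 with dHet proB library 3 and that use only library 2 of each B-ALL mouse were chosen after seeing the data. Over all settings, 4797 values of named genes kept their direction and side of the threshold, 380 lost the call, 25 gained it and 11 changed sign, none of these past the test. Lists did so 1797, 68, 63 and 4 times, and counts stayed within 1.5 times of their value 236 times, fell below 31 times and rose above 15 times. With only library 2 of each mouse every count stayed within that range. The depth is unknown and limits low values in a way that cannot be measured here.

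Without a filter, 1181 genes were lower in dHet proB than in wt proB, and the median of the stromal list was 0, since more genes near 0 were tested. With a filter of FPKM 5, 739 were lower in B-ALL and 390 in dHet proB against wt proB, since fewer genes were tested. Rescaling to TPM gave 529 higher and 1695 lower in B-ALL against wt proB and 347 and 750 against both groups, and turned Mthfd2 against wt proB to -0.13. Quantile normalization gave 505 genes higher in dHet proB and turned Mthfd2 to -0.0738. Taking all 11 libraries as independent samples gave 1638 and 1689 against wt proB and 1210 and 831 against both, since it counts each mouse more than once. With a replicate block added to these 11 libraries, 1603 genes were higher against wt proB and 1063 and 708 differed from both groups. In that setting Rag1 in dHet proB against wt proB turned to -0.16 and the cell cycle list to 0.14. The replicate numbers do not pair the libraries by any label, and deviations of libraries with the same number correlated across genes by a median r of 0.06, and by 0.64, 0.20 and 0.13 between the B-ALL mice. Without mouse 713 and dHet proB library 3, 1425 genes were higher against wt proB and 1029 and 701 differed from both. In dHet proB against wt proB Rag1 turned to -0.16 and the cell cycle list to 0.14. With an estimated correlation 2 instead of 27 list tests passed and with fry 32, and with only the 6 B-ALL libraries 5073 genes differed between mice. Except where the construction is named, the cause was not tested.

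Leaving out each library or mouse gave 61 to 1113 higher and 134 to 1359 lower in B-ALL against wt proB, 810 to 1664 and 582 to 1301 against dHet proB, 13 to 328 and 63 to 923 in dHet proB against wt proB, 52 to 810 and 66 to 578 against both, and 1302 to 3430 between mice. Values that changed sign ranged from -0.0536 to 0.24 for Mthfd2 in B-ALL against wt proB. In dHet proB against wt proB they ranged from -0.79 to 0.0771 for Ebf1, -0.23 to 0.57 for Pax5, -0.16 to 0.42 for Rag1, -1.84 to 0.56 for Myc, -0.59 to 0.0281 for Shmt2 and -0.47 to 0.14 for the cell cycle list. Without a wt proB library that group is left with 1 library.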

Other observations

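The genes in this part were chosen after their values were seen, and no test of them is reported. The predicted gene Gm525 had 57.5 and 53.7 FPKM in mouse 686, 900 and 811 in mouse 713 and 1830 and 1330 in mouse 760. It had at most 0.110 in dHet proB and 2.26 and 3.01 in wt proB. Rnase6, another member of the ribonuclease A family, ran the other way from Rnase12, with 148 and 90.3 FPKM in wt proB against 2.37 to 24.0 in B-ALL. Asns, which makes asparagine, had 9.41, 36.3 and 8.10 FPKM in dHet proB and 1.94 and 2.13 in wt proB, and 0.257 or less in every B-ALL library. The metallothionein gene Mt1 had 317 and 312 FPKM in mouse 686 and 192 to 460 in dHet proB, against 42.9 to 61.5 in the other leukemic mice and 20.5 to 23.9 in wt proB.

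In dHet proB library 3 the lymphotoxin gene Lta had 302 FPKM, against 0.860 and 0.301 in libraries 1 and 2, and the secretory factor Xbp1 had 772 against 50.8 and 54.2. Lta was also listed at 155 and 157 in mouse 713, 30.8 and 30.4 in mouse 686 and 3.76 and 5.77 in mouse 760. Xist was listed above 1 FPKM, with Ddx3y below 1, in mouse 760 and in dHet proB libraries 1 and 3, and the reverse held in all other libraries. B-ALL and dHet proB thus each hold libraries of both kinds, and wt proB holds only the kind with Ddx3y.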
